A study of Homo sapiens with 8 samples.

How the data were processed

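The samples were 8 arrays of total RNA from BE(2)-C cells, in 4 groups of 2: DMSO and 5, 10 and 15 nM panobinostat, each for 24 h. Per the labels, the RNA was purified on columns with a DNase step, labelled with Cy3 and hybridised to Agilent miRNA arrays in 1 colour. Groups and replicate numbers were taken from the labels. These give 2 independent experiments, and replicate 1 of every group lay on 1 slide and replicate 2 on the other, so the replicate number, the experiment and the slide are the same split and pair the samples. The p-values measure the spread between these 2 experiments. Per the array names, each group also had the same position on both slides, so slide position and dose cannot be told apart. As a check of the pairing, the deviations of same-numbered arrays from their group means correlated across miRNAs at 0.665 for DMSO with 5 nM, 0.301 for DMSO with 10 nM, -0.40 for DMSO with 15 nM, 0.444 for 5 with 10 nM, -0.094 for 5 with 15 nM and 0.404 for 10 with 15 nM. The check thus did not bear out the pairing of the 15 nM arrays with the DMSO or the 5 nM arrays. Differences within a slide at 15 nM rest on the labels alone.

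Spot intensity was deposited as scanner output of Agilent Feature Extraction 10.7.3.1, per the file headers; the processed signal used here was background-subtracted by that program and was not normalized between arrays. The authors also deposited a table per slide with a mean raw intensity and a detection p-value per probe. The test behind those p-values is not given in the sources used here, and they entered no result. The raw means, quantile normalized here, were an alternative input. The scanner files used here hold no mean signal column, so the alternative with normexp (offset 50) used the median signal and the local background median. That offset by itself shrinks the log2 changes of dim miRNAs, so smaller changes with normexp were bound to follow for them. The array design names the genome build hg19, per the file headers, and no coordinates are given. miRNA names are those of the array design and can be old. A reference gene table (GRCh38.p14) was used only for the order of miRNA genes on chromosome 14, where all 50 measured C14MC members had a match.

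Control spots and spots flagged as outliers were left out, except where all spots of a probe on an array were flagged. Signals were scaled on each array to the 75th percentile over the spots of the 595 probes, of 5893, that were detected on all 8 arrays. That percentile ranged from 250.6 to 416.6 before scaling. Scaled signals were floored at 19.9, percentile 1 of the scaled signals of spots well above background, and log2 transformed, and the 5 to 20 spots of a probe were averaged. A miRNA had 1 to 4 probes, and the probe with the highest mean over all arrays stood for it. A probe was detected on an array if a share of over 0.5 of its spots was well above background, and a miRNA was tested if detected on both arrays of at least 1 group. A miRNA not well above background on either array of a group has only a bound there. Its fold is given as at least the ratio of the brighter group's mean to the dimmer group's mean of, per array, the higher of the lowest detected probe signal and its own signal, on the log2 scale. Values at the floor have no order.

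The tests used lmFit and eBayes of limma 3.58.1 in R 4.3.3 (files were read with version 1.17.8 of data.table) on all 8 arrays with a mean per group and a pooled spread, with 4 residual and 3.14 prior degrees of freedom. The threshold was a Benjamini-Hochberg adjusted p of 0.05. The contrasts were each dose with DMSO, the mean of the 3 doses with DMSO, 15 with 5 nM, and a linear slope on dose. The 19 miRNA lists, the tests and the rule for named miRNAs were written before the data were examined. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera compares a list with the other tested miRNAs, while fry tests it against no change. The lists are the miR-17-92 and paralog clusters, let-7 and miR-98, miR-30, p53-induced, miR-183-96-182, miR-15 and miR-16, miR-29, miR-26, the miR-23, miR-27 and miR-24 clusters, neuron-enriched, C14MC, C19MC, the miR-371 and miR-302 clusters, Xq27.3, miR-200, miR-449, mesenchymal, blood cell, and muscle and liver miRNAs. Named for each dose were up to 10 largest rises and falls among called miRNAs with both arrays on the same side of both DMSO arrays, or the 5 smallest p-values in a direction without calls. Named otherwise were the 5 largest per direction in the other comparisons, the 2 members with the smallest p per list for the mean of the 3 doses, and the measured members of the miR-30 family, the miR-183-96-182 cluster and miR-34a.

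The fit was tested on simulated data for the comparison of 15 nM with DMSO over 396 miRNAs: in 20 draws 59.5% of simulated log2 changes of 0.5, 96.2% of 1 and 99.5% of 2 were recovered, and 4.93% of calls were false. The simulated noise was independent between miRNAs and between arrays, with no slide effect. The arrays used here shared deviations, so their share of false calls can differ. The alternatives were normexp background, the percentile over all probes, quantile normalization, no scaling, the mean of all probes, the scanner software's total gene signal, no filter, miRNAs detected on all 8 arrays, a floor 4 times lower, the slide as a replicate block, only the 2 groups compared, an intensity trend, and each array left out in turn. Leaving out an array leaves its group with 1, which is then assumed to vary like the other groups. Without a filter, 1873 of 2549 miRNAs were constant on all arrays within 1e-09 on the log2 scale. A first fit called differences of rounding error among them, so they were left out of that alternative after its outcome was seen, and 676 miRNAs were tested. Alternatives chosen after seeing the data were the deposited raw means, scaling to the labelling spike-ins with the slide as a block, and a crossed pairing of the 15 nM arrays. Groups of 2 are too small for a test of outlying samples.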

Results

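MicroRNA levels were measured in BE(2)-C cells, an established human neuroblastoma line with amplified MYCN, after 24 h with the solvent DMSO or with 5, 10 or 15 nM panobinostat, an inhibitor of histone deacetylases. Each of the 4 groups held 2 arrays, from 2 independent experiments, and each experiment was hybridised on its own slide. Of the 2549 human miRNAs on the array, 396 were well above background on both arrays of at least 1 group and were tested. Between 338 and 433 miRNAs were detected per array, and no spot was saturated. The number of arrays limits the precision. The correlation of the 2 arrays of a group over the tested miRNAs ranged from 0.984 in DMSO to 0.997 at 10 nM. The first principal component held 70.5% of the variance, and both 15 nM arrays, at 8.44 and 5.40, lay beyond all others on it, while the DMSO arrays lay at -6.67 and -1.75. Changes are differences of mean log2 scaled signal, and adjusted p-values are from limma with Benjamini-Hochberg adjustment over the 396 miRNAs.

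The comparison of 15 nM with DMSO asked what the highest dose did. miR-5703 went from a log2 signal of 4.71 ± 0.23 (SD, n = 2) in DMSO to 7.54 ± 0.28 (SD, n = 2), a 7.11-fold rise (log2 fold change 2.83, SE 0.18, adjusted p = 0.000265 by limma). The floor is 4.32 on this scale, so its DMSO signal lay close to the floor and the size of the fold is uncertain. miR-630 rose 7.02-fold (log2 2.81, SE 0.20), miR-575 4.17-fold (log2 2.06, SE 0.31) and miR-129-2-3p, a brain-enriched miRNA, 4.02-fold (log2 2.01, SE 0.14). miR-5787, miR-6821-5p and miR-7150 rose by 1.67, 1.64 and 1.57 on the log2 scale. miR-3940-5p, miR-3663-3p and miR-4446-3p, each well above background on 1 of the 2 DMSO arrays, rose by 1.58, 1.58 and 1.53. Falls were smaller. miR-543 fell from 7.21 ± 0.13 (SD, n = 2) to 5.93 ± 0.06 (SD, n = 2), or 2.42-fold (log2 fold change -1.27, SE 0.10, adjusted p = 0.00031 by limma). miR-483-3p, encoded within the IGF2 gene, was 2.20-fold lower, miR-485-3p 2.14-fold, miR-154-3p 2.12-fold, miR-17-3p 1.95-fold, miR-495-3p 1.93-fold and miR-431-5p 1.89-fold. The log2 fold changes of miR-3132, miR-18a-5p and miR-92a-3p were -0.79, -0.69 and -0.68. With normexp background correction the rises shrank to 1.51 for miR-5703, 1.73 for miR-630, 1.24 for miR-575, 1.02 for miR-129-2-3p, 0.91 for miR-7150, 0.70 for miR-3663-3p, 0.67 for miR-4446-3p and 0.65 for miR-3940-5p, and the falls to -0.81 for miR-543, -0.62 for miR-17-3p, -0.52 for miR-485-3p and -0.42 for miR-3132. With the mean of all probes miR-4446-3p had 0.80, miR-3940-5p 0.79 and miR-485-3p -0.68, and with the total gene signal miR-485-3p had -1.71. Without replicate 1 of DMSO miR-5787 and miR-7150 had 1.04 and 1.03; on slides 1 and 2 miR-5787 had 2.51 and 0.84, and miR-7150 2.46 and 0.68.

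In all, 73 miRNAs were higher and 80 lower at 15 nM (limma, adjusted p under 0.05), and 192 had an unadjusted p under 0.05. More than 2-fold changes were found for 33 of the higher and 4 of the lower miRNAs. Of the 73 higher miRNAs, 59 carried miRBase numbers over 600, against 14 of the 80 lower ones. The 73 higher miRNAs had a median difference of 1.23 on slide 1 and 0.62 on slide 2, and over them the DMSO array of slide 2 lay a median of 0.33 above that of slide 1. The 80 lower ones had medians of -0.57 and -0.36, and over them the DMSO array of slide 2 had a median of -0.12 relative to that of slide 1. Another probe was detected on all arrays for 109 of the 153 miRNAs, and for all 109 it moved the same way. In a fit on the 323 miRNAs detected on all 8 arrays, 53 were higher and 70 lower. Of the 153 calls 127 were tested in that fit. Without scaling 41 miRNAs were higher and 12 lower, and with scaling to the labelling spike-ins 59 and 10; miR-18a-5p lost its call under both and miR-3132 under the latter. The count of 153 became 81 without replicate 1 of DMSO, 59 without replicate 1 of the 15 nM group and 68 in a fit on these 2 groups alone. The call on miR-5787 was lost without either 15 nM array, that on miR-7150 also without replicate 1 of DMSO, and that on miR-3663-3p without replicate 1 of the 15 nM group and with the scanner software's total gene signal. miR-5787 and miR-7150 also lost it with no filter. The median of all 396 miRNAs was -0.05, and 0.13 with spike-in scaling.

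**Figure D1:**
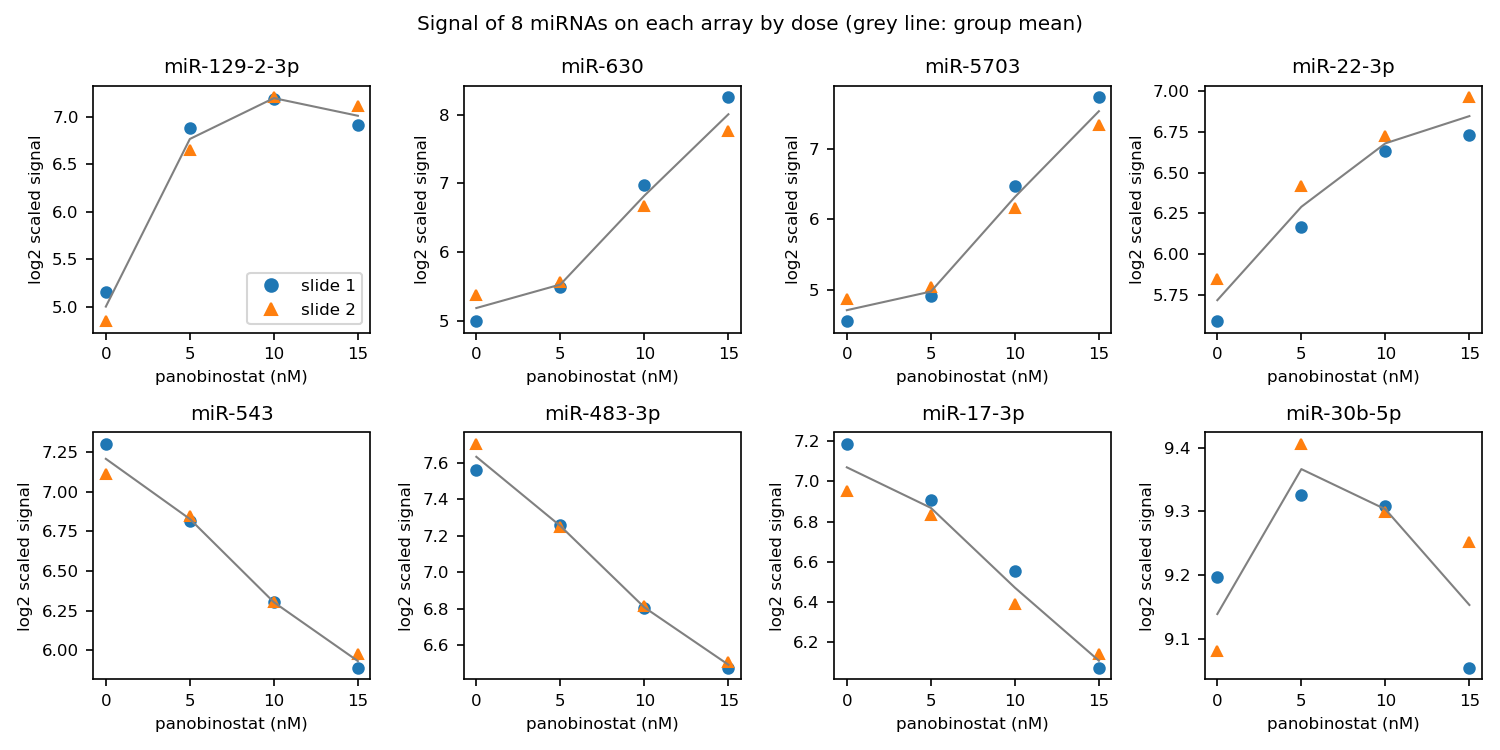
Log2 scaled signal (y axis) of 8 miRNAs against panobinostat dose in nM (x axis); circles are slide 1, triangles slide 2, and the grey line joins the group means. miR-129-2-3p was 1.76 above DMSO at 5 nM and 2.01 at 15 nM, miR-630 was 2.81 above it at 15 nM, and miR-543 had a log2 fold change of -1.27 there.

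**Figure D2:**
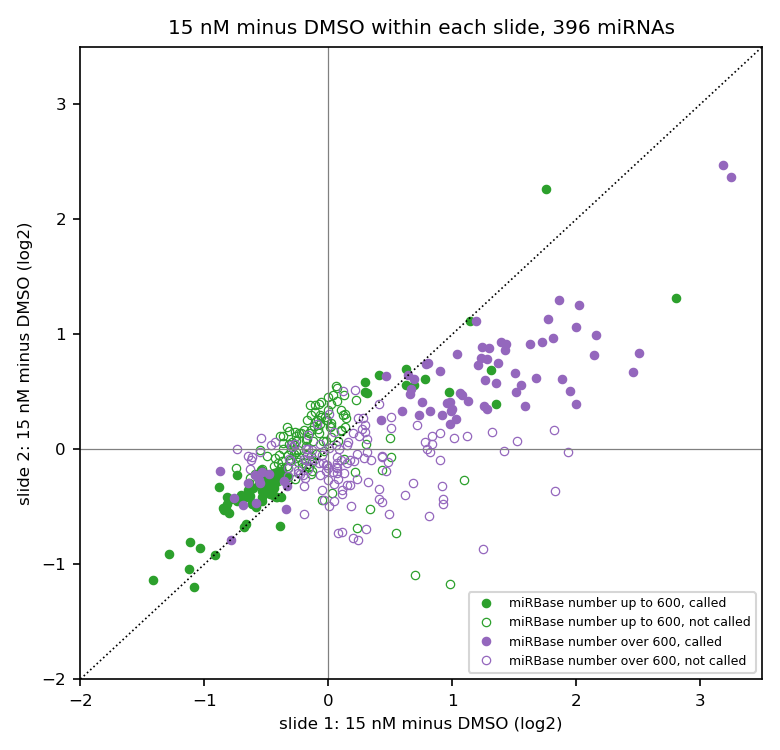
Log2 difference of 15 nM minus DMSO on slide 2 (y axis) against slide 1 (x axis) for the 396 tested miRNAs, coloured by miRBase number up to or over 600; filled points passed the test and the dotted line marks equal values. The higher miRNAs had a median of 1.23 on slide 1 and 0.62 on slide 2.

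Among the lists fixed before the data were examined, members of the miR-17-92 cluster and its paralogs, which MYC and MYCN activate, were lower at 15 nM. Of 14 measured members 12 fell and 0 rose, and 14 were lower when adjusted over the list alone. miR-17-3p, miR-18a-5p and miR-92a-3p had log2 fold changes of -0.96, -0.69 and -0.68, and miR-19b-1-5p, not well above background on either 15 nM array, was at least 1.40-fold lower. The median was -0.60, with -0.76 on slide 1 and -0.44 on slide 2 (camera, adjusted p = 3.31e-06). With an estimated correlation the adjusted p was 0.715. The median lay between -0.43 and -0.66 under the scalings tried, but only 3 members were lower without scaling or with spike-in scaling. In DMSO the array of slide 2 had a median of -0.22 relative to that of slide 1 over these members, with 14 of 14 below 0. Near-identical members can bind each other's probes, so single members are uncertain. Camera compares a list with all other tested miRNAs. At 15 nM the 200 with miRBase numbers over 600 had a median of 0.12. The 196 with numbers up to 600, which include all members of this list, had -0.17.

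C14MC, the imprinted DLK1-DIO3 region of chromosome 14 whose miRNAs are abundant in brain, had 50 measured members, of which 28 fell at 15 nM. When adjusted over the list alone 30 were lower. The fallers include 5 of the 10 miRNAs named above for the largest falls, miR-543, miR-485-3p, miR-154-3p, miR-495-3p and miR-431-5p. The 1 member that rose was miR-2392 (log2 fold change 0.60, adjusted p = 0.0431 by limma), named after its value was seen and detected on 1 DMSO array. The median was -0.35, with -0.44 on slide 1 and -0.25 on slide 2 (camera, adjusted p = 6.86e-11). With an estimated correlation the adjusted p was 0.712. The median lay between -0.16 and -0.41 under the scalings tried, with 6 members lower without scaling and 5 with spike-in scaling. Relative to the median of all miRNAs it was -0.31, and -0.29 with spike-in scaling. The DMSO array of slide 2 had a median of -0.07 relative to that of slide 1 over these members, with 38 of 50 below 0. Most members carry miRBase numbers up to 600, and the 196 such miRNAs tested had a median of -0.17 at 15 nM.

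Of 10 measured let-7 and miR-98 members, a family that accumulates with differentiation, 7 fell at 15 nM and 8 were lower when adjusted over the list alone. let-7b-5p fell by 0.41 on the log2 scale, and let-7a-3p, detected on 1 of the 2 15 nM arrays, by 0.60. The median was -0.32 (camera, adjusted p = 0.00482), and with an estimated correlation the adjusted p was 0.715. It lay between -0.13 and -0.37 under the scalings tried, with 1 member lower under quantile normalization, without scaling and with spike-in scaling. The DMSO array of slide 2 had a median of -0.14 relative to that of slide 1, with 10 of 10 members below 0. These sequences also are near identical. All members belong to the 196 tested miRNAs numbered up to 600, whose median at 15 nM was -0.17. The list was not tested against these alone.

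**Figure D3:**
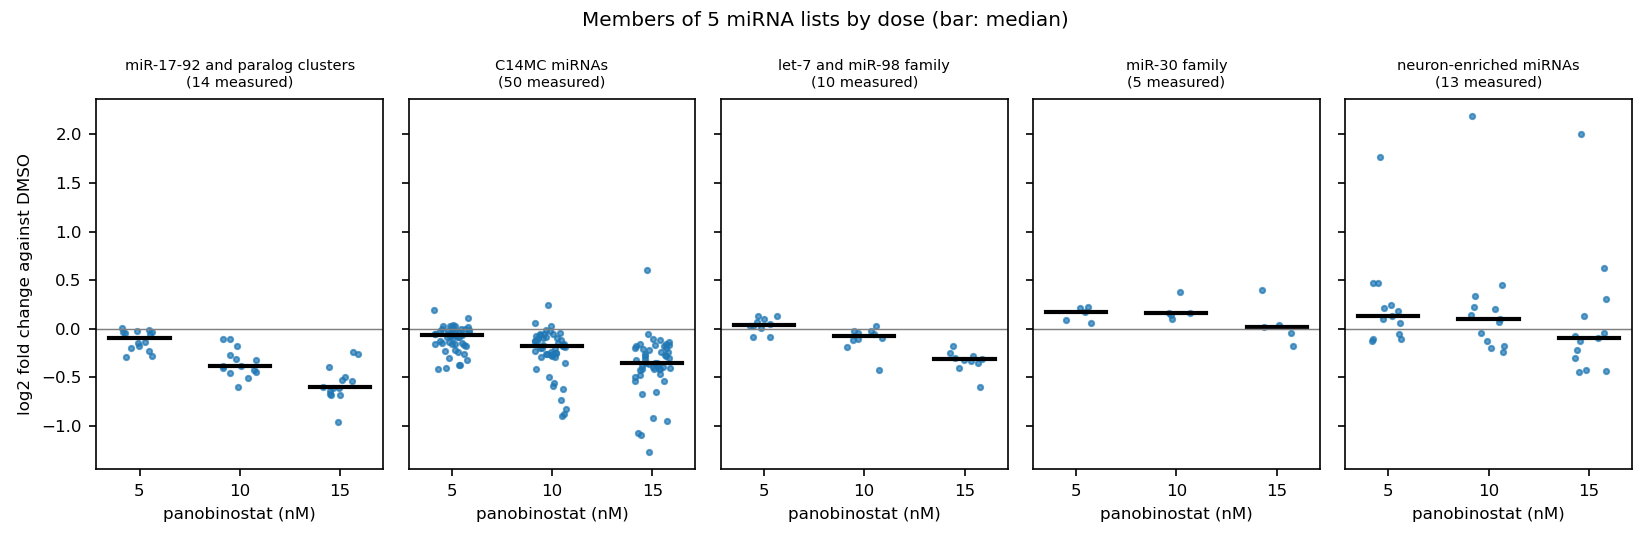
Log2 fold change against DMSO (y axis) of each measured member of 5 miRNA lists at 5, 10 and 15 nM (x axis); each point is a miRNA and the bar is the median. At 15 nM the medians were -0.60 for the miR-17-92 list, -0.35 for C14MC and -0.32 for let-7; that of the miR-30 family, 0.01, was -0.04 with the percentile over all probes, and that of the neuron-enriched list, -0.10, was 0.10 with spike-in scaling.

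The calls at 15 nM in the lists that follow are named after their values were seen. Of 13 neuron-enriched miRNAs, miR-129-2-3p and miR-7-5p rose, the latter by 0.63 on the log2 scale, and miR-10b-5p, miR-137 and miR-218-5p fell by 0.45, 0.43 and 0.31. Of 7 mesenchymal miRNAs, miR-22-3p rose by 1.13, and miR-199a-5p, miR-214-3p and miR-199a-3p fell by 0.42, 0.40 and 0.38. miR-16-2-3p fell by 0.48 among 8 members of the miR-15 and miR-16 family, miR-29b-3p fell by 0.29 among 3 of the miR-29 family (adjusted p = 0.0471 by limma, and 0.0514 with the replicate block), and miR-371b-5p rose by 0.87, while miR-371a-5p, the other measured member of its list, had 0.17 and did not pass. When adjusted over the list alone, the neuron-enriched list had 2 higher and 4 lower members, the mesenchymal list 1 and 3, and the miR-15 and miR-16 and miR-29 families 0 of either, against 1 lower in each by limma over all miRNAs. The neuron-enriched list had a mean of 0.07 and a median of -0.10, which was 0.10 with spike-in scaling, and none of these 4 lists passed (camera, adjusted p from 0.667 to 0.728).

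The title of the study concerns AVEN, an inhibitor of apoptosis, and the miR-30 family, the miR-183-96-182 cluster and miR-34a were set to be given in full. At 15 nM the log2 fold changes of miR-30b-5p, miR-30c-5p, miR-30d-5p and miR-30e-5p were 0.01, -0.18, 0.04 and -0.05, and none passed (adjusted p = 0.928, 0.300, 0.853 and 0.753 by limma). Each of these 4 values changed sign under at least 1 scaling, as miR-30c-5p did to 0.02 and miR-30e-5p to 0.15 with spike-in scaling, and miR-30b-5p to -0.04 and miR-30d-5p to -0.02 with the percentile over all probes. Without replicate 2 of the 15 nM group miR-30b-5p and miR-30d-5p had -0.09 and -0.16, and without replicate 1 of DMSO miR-30e-5p had 0.04. miR-30a-5p, not well above background on either DMSO array, was at least 1.23-fold higher (adjusted p = 0.0221 by limma). That call was lost with normexp, quantile normalization, no scaling, the mean of all probes and only the 2 groups, and without replicate 1 of DMSO or of the 15 nM group. miR-96-5p, not well above background on either DMSO array, was at least 1.47-fold higher at 15 nM (adjusted p = 0.00271 by limma) and at least 1.24-fold at 10 nM (adjusted p = 0.0478, and 0.0547 with the replicate block). Its difference between 5 nM and DMSO was 0 on both slides, so both groups lay at the floor. These groups added no spread to its test, and its SE was 0.092 against a median of 0.132 over all miRNAs. Its p-values are thus too low to be read as replicate spread. miR-183, miR-182 and miR-34a were detected on 0 of the 8 arrays.

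At 10 nM, 12 miRNAs were higher and 11 lower than in DMSO (limma), and 98 had an unadjusted p under 0.05. miR-129-2-3p rose 4.57-fold (log2 2.19, SE 0.14, adjusted p = 0.00038 by limma), with 2.03 on slide 1 and 2.36 on slide 2. miR-630 and miR-5703 rose by 1.63 and 1.61 on the log2 scale, and miR-22-3p, miR-4485-3p, miR-3940-5p, miR-6821-5p and miR-185-5p by 0.96, 0.90, 0.84, 0.78 and 0.63. miR-181a-3p and miR-937-5p, not well above background on either DMSO array, were at least 1.47-fold and 1.40-fold higher. The falls were led by miR-543 at -0.90, miR-485-3p at -0.88, miR-154-3p and miR-483-3p at -0.83, miR-431-5p at -0.74, miR-495-3p at -0.62, miR-17-3p at -0.60 and miR-134-5p at -0.59. miR-431-3p and miR-19b-1-5p, not well above background on the 10 nM arrays, were at least 1.44-fold and 1.27-fold lower. The SEs of miR-181a-3p, miR-937-5p, miR-431-3p and miR-19b-1-5p were 0.1215, 0.0869, 0.0885 and 0.103, against a median of 0.132 over all miRNAs. Whether values at the floor lowered them was not tested. With normexp miR-129-2-3p had 1.17, miR-630 0.86, miR-5703 0.71, miR-22-3p 0.54, miR-6821-5p 0.50, miR-3940-5p 0.34, miR-185-5p 0.32, miR-543 -0.56, miR-17-3p -0.38, miR-485-3p -0.37 and miR-134-5p -0.26. The deposited means gave 0.98 for miR-5703, 0.63 for miR-22-3p, 0.52 for miR-3940-5p and 0.32 for miR-185-5p, the mean of all probes 0.42 for miR-3940-5p and -0.57 for miR-485-3p, and the total gene signal -1.41 for miR-485-3p.

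Leaving out an array also lowers the residual degrees of freedom, even for arrays outside the contrast, so a lower count need not reflect that array. The count of 23 at 10 nM changed when single arrays were left out. It was 1 and 3 without replicate 1 or 2 of the 10 nM group, 13 and 45 without replicate 1 or 2 of DMSO, and 12 and 13 without replicate 1 or 2 of the 5 nM group. It was 1 in a fit on these 2 groups alone and with spike-in scaling, 3 without scaling, 11 with the percentile over all probes and 14 with quantile normalization. Among the miRNAs named for 10 nM, miR-129-2-3p alone kept its call under every alternative and without each array, and miR-6821-5p lost it with the replicate block (adjusted p = 0.0646).

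All 23 miRNAs called at 10 nM were also called at 15 nM in the same direction, 12 higher and 11 lower. Independent lists of these sizes would share 2.21 higher and 2.22 lower. In 100 simulations with no change in any group and simulated DMSO arrays in common, 0.01 were shared on average. Almost no miRNA is called without a change, so that count does not give the overlap due to shared DMSO arrays. The simulated correlations that follow come from the shared arrays alone. The correlation of log2 fold changes at 15 and 10 nM across miRNAs, which are not independent replicates, was 0.853, against 0.490 in the simulations, with a covariance of 0.159 against 0.0144. Part of the excess may come from the shared DMSO arrays, which were too few to split. For 15 with 5 nM the correlation was 0.336, below the 0.511 of the simulations, with a covariance of 0.0378 against 0.0151. For 10 with 5 nM it was 0.691 against 0.494, with a covariance of 0.0450 against 0.0145. Each of these pairs shared 1 call, miR-129-2-3p.

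At 5 nM miR-129-2-3p was the 1 miRNA that passed the test, 3.39-fold higher than in DMSO (log2 1.76, SE 0.14, adjusted p = 0.00172 by limma), and 41 had an unadjusted p under 0.05. With normexp its log2 fold change was 0.94. Its difference between 15 and 5 nM was 0.24 on the log2 scale and did not pass (adjusted p = 0.203 by limma). The smallest p-values among lower miRNAs, none of which passed, belonged to miR-431-3p, miR-483-3p, miR-431-5p, miR-543 and miR-4449, with log2 fold changes of -0.42, -0.38, -0.41, -0.38 and -0.35 (adjusted p from 0.187 to 0.283), of which miR-431-3p and miR-4449 turned to 0.05 and 0.03 with normexp. Without scaling the 5 were -0.60, -0.72, -0.75, -0.72 and -0.63, and none passed (adjusted p from 0.284 to 0.321 by limma). miR-431-3p passed with no filter (adjusted p = 0.0298), and miR-431-5p with the mean of all probes, at -0.55 (adjusted p = 0.0301). The miR-129-2-3p call was lost without replicate 2 of the 15 nM group, where 0 miRNAs passed in limma and 65 had an unadjusted p under 0.05, and in a fit on the DMSO and 5 nM arrays alone, where 0 passed in limma and 32 had an unadjusted p under 0.05. The median of all 396 miRNAs was 0.05 at 5 nM, and -0.27 without scaling.

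The lists were also tested at the lower doses. At 10 nM the medians of C14MC and miR-17-92 were -0.19 and -0.38 (camera, adjusted p = 3.73e-14 and 3.47e-08), with 8 and 2 members lower and 9 in each when adjusted over the list alone. With an estimated correlation the adjusted p was 0.476 and 0.523. At 5 nM they were -0.07 and -0.09 (camera, adjusted p = 2.82e-10 and 0.000325, and 0.541 for both with an estimated correlation), with 0 members lower by either adjustment. These 2 medians at 5 nM were -0.41 and -0.40 without scaling, -0.26 and -0.29 with spike-in scaling, -0.22 and -0.25 with the percentile over all probes and -0.11 and -0.19 with quantile normalization, and with normexp C14MC had -0.0091 and with the deposited means miR-17-92 had -0.19. Relative to the median of all miRNAs they were -0.11 and -0.14, and -0.14 and -0.13 without scaling. The let-7 list did not pass at either dose. Its median was -0.08 at 10 nM (camera, adjusted p = 0.114) and 0.04 at 5 nM with 8 of 10 members above 0 (adjusted p = 0.980), and the latter was -0.29 without scaling, -0.16 with spike-in scaling and -0.12 with the percentile over all probes.

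At 5 nM 3 other lists passed in the upward direction, and they did not pass at 10 or 15 nM. The miR-23, miR-27 and miR-24 clusters had a median of 0.27 (camera, adjusted p = 0.0131, and 0.541 with an estimated correlation), which was -0.07 without scaling. The mesenchymal list had 0.18 with 7 of 7 members above 0 (adjusted p = 0.0175, and 0.541 with an estimated correlation), which was -0.16 without scaling and -0.02 with spike-in scaling. The neuron-enriched list had 0.13 (adjusted p = 0.0241, and 0.541 with an estimated correlation), which was -0.21 without scaling, -0.06 with spike-in scaling and -0.02 with the percentile over all probes. In limma miR-129-2-3p was the 1 called member, and when adjusted over the list alone 0, 1 and 3 members were higher. miR-23a-3p, miR-22-3p and miR-9-3p, chosen after their values were seen, had 0.37, 0.57 and 0.47 and did not pass (adjusted p = 0.289, 0.187 and 0.187 by limma). The medians of the mesenchymal and neuron-enriched lists were -0.34 and -0.10 at 15 nM, where the latter was 0.10 with spike-in scaling. In the direct test of 15 with 5 nM these 3 lists did not pass by camera (adjusted p = 0.288, 0.185 and 0.234). By fry the mesenchymal and neuron-enriched lists passed downward there (adjusted p = 0.0407 and 0.0490), and the miR-23, miR-27 and miR-24 clusters did not (0.146). Fry tests against no change, so a shift of all miRNAs enters it. The median of all 396 was -0.13 in that comparison, 0.29 without scaling and 0.25 with spike-in scaling.

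The direct comparison of 15 with 5 nM found 66 miRNAs higher and 77 lower at 15 nM (limma). miR-5703 was 2.57 higher on the log2 scale, miR-630 2.47, miR-575 1.82 and miR-5787 1.60. miR-4446-3p, not well above background on either 5 nM array, was also higher. The lower ones were led by miR-543 at -0.90, miR-17-3p and miR-483-3p at -0.76, miR-154-3p at -0.75 and miR-485-3p at -0.72. With normexp miR-5703 had 1.24, miR-630 1.46, miR-575 1.05 and miR-485-3p -0.46, and with the mean of all probes miR-485-3p had -0.42. The median of all 396 miRNAs was -0.13, and it was 0.29 without scaling and 0.25 with spike-in scaling. Without scaling 69 miRNAs were higher and 0 lower, with spike-in scaling 71 and 1, and with the percentile over all probes 65 and 16; each of these 5 named falls lost its call without scaling, and all but miR-543 with spike-in scaling. Without scaling miR-543, miR-17-3p, miR-483-3p, miR-154-3p and miR-485-3p had -0.45, -0.32, -0.32, -0.31 and -0.28, and with spike-in scaling -0.50, -0.37, -0.37, -0.36 and -0.33. The count of 143 fell to 21 and 50 without replicate 1 or 2 of the 5 nM group, to 22 without replicate 1 of the 15 nM group and to 87 without replicate 1 of the 10 nM group; the calls on miR-575 and miR-17-3p were lost without replicate 1 of either the 5 or the 15 nM group, that on miR-154-3p without replicate 1 of the 5 nM group, that on miR-5787 with no filter and without either 5 nM or either 15 nM array, and that on miR-485-3p without either 5 nM array or replicate 1 of the 15 nM group.

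By camera at the preset correlation, C14MC, miR-17-92 and let-7 were the 3 of 10 lists that passed between 15 and 5 nM. They also passed by fry (adjusted p = 0.0131 for each). The miR-29, mesenchymal and neuron-enriched lists passed downward by fry alone (adjusted p = 0.0131, 0.0407 and 0.0490). Fry does not set a list against the other miRNAs, and the median of all 396 was itself -0.13. C14MC had a median of -0.26, which was 0.17 without scaling and 0.13 with spike-in scaling (camera, adjusted p = 2.41e-05, and 0.729 with an estimated correlation). Of its members 16 were lower and 15 when adjusted over the list alone, and 1 was higher, miR-2392, not well above background on either 5 nM array. The miR-17-92 list had a median of -0.50, with 9 of 14 members lower and 10 when adjusted over the list alone (adjusted p = 0.000476, and 0.729 with an estimated correlation). That median was -0.08 without scaling and -0.12 with spike-in scaling. The let-7 list had a median of -0.40, which was 0.04 without scaling and -0.0069 with spike-in scaling, with 7 of 10 members lower and 9 when adjusted over the list alone (adjusted p = 0.00650, and 0.729 with an estimated correlation). With spike-in scaling 1 member of C14MC and 0 of the other 2 lists were lower, and without scaling 0 of any in limma, where 111 of the 396 miRNAs had an unadjusted p under 0.05 in either direction.

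A linear slope on dose was positive for 75 miRNAs and negative for 82 (limma). The steepest rises per 5 nM were 0.98 for miR-5703, 0.97 for miR-630, 0.71 for miR-575, 0.65 for miR-129-2-3p and 0.56 for miR-5787 on the log2 scale. A called slope need not be a graded rise. miR-129-2-3p was 1.76, 2.19 and 2.01 above DMSO at 5, 10 and 15 nM, most of it reached at 5 nM. The steepest falls were -0.43 for miR-543, -0.39 for miR-483-3p, -0.38 for miR-485-3p, -0.37 for miR-154-3p and -0.33 for miR-17-3p. With normexp the slopes were 0.50 for miR-5703, 0.58 for miR-630, 0.41 for miR-575, 0.33 for miR-129-2-3p, -0.28 for miR-543, -0.19 for miR-485-3p and -0.22 for miR-17-3p. For miR-485-3p the mean of all probes gave -0.23 and the total gene signal -0.59. With the total gene signal, where 511 miRNAs were tested, 79 slopes were positive and 131 negative. Without scaling 64 slopes were positive and 13 negative, with spike-in scaling 79 and 13, and 87 in all passed without replicate 1 of the 15 nM group. The slope of miR-5787 lost its call with no filter and without either 15 nM array, and was 0.37 without replicate 1 of DMSO.

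Averaged over the 3 doses, 29 miRNAs were higher and 21 lower than in DMSO (limma). miR-129-2-3p was 1.99 higher on the log2 scale, miR-630 1.60, miR-5703 1.57 and miR-22-3p 0.89. miR-937-5p, not well above background on the DMSO arrays, was also higher. Its SE was 0.071, against a median of 0.107 over all miRNAs, and whether values at the floor lowered it was not tested. miR-543 was lower at -0.85, miR-485-3p at -0.79, miR-483-3p at -0.78, miR-154-3p at -0.75 and miR-431-5p at -0.69. With normexp miR-129-2-3p had 1.04, miR-630 0.95, miR-5703 0.83, miR-22-3p 0.52, miR-543 -0.52 and miR-485-3p -0.32. The deposited means gave 1.03 for miR-5703 and 0.59 for miR-22-3p, and miR-485-3p had -0.50 with the mean of all probes and -1.25 with the total gene signal. The count of 50 became 16 and 81 without replicate 1 or 2 of DMSO, 28 and 22 without replicate 1 or 2 of the 5 nM group, 18 and 17 without replicate 1 or 2 of the 10 nM group, and 31 without replicate 1 of the 15 nM group. It was 8 without scaling and with spike-in scaling, 28 with the percentile over all probes and 32 with quantile normalization. miR-937-5p and miR-154-3p lost their calls without scaling, miR-483-3p and miR-431-5p with spike-in scaling, and miR-485-3p with normexp and without replicate 1 of DMSO.

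In the test of 10 lists for the mean of the 3 doses, 3 passed, all lower. C14MC had a median of -0.19, with 11 of 50 members lower and 14 when adjusted over the list alone (camera, adjusted p = 1.64e-14, and 0.458 with an estimated correlation). Its median was -0.30 without scaling and -0.37 with the total gene signal. The miR-17-92 list had a median of -0.37, with 6 of 14 lower and 11 when adjusted over the list alone (adjusted p = 7.93e-08, and 0.556 with an estimated correlation), and the median was -0.24 without replicate 1 of DMSO. The let-7 list had a median of -0.11 with 0 of 10 members lower by either adjustment (adjusted p = 0.0336, and 0.970 with an estimated correlation), and 0 passing in limma. That median was -0.03 and -0.19 without replicate 1 or 2 of DMSO, -0.20 with the percentile over all probes, -0.22 without scaling and -0.24 with the total gene signal. By dose its median was 0.04 at 5 nM, where it was below 0 under 3 scalings, -0.08 at 10 nM and -0.32 at 15 nM, and the list passed at 15 nM alone. With an estimated correlation 0 lists passed. The let-7 call was also lost with fry (adjusted p = 0.152), under 6 alternatives with adjusted p from 0.0523 to 0.215, without replicate 1 of DMSO (adjusted p = 0.504) and without replicate 2 of the 5 or 10 nM group (0.0699 and 0.0535). miR-17-3p was lower at -0.59, or -0.36 with normexp, a call lost without scaling, with spike-in scaling and without replicate 1 of DMSO. miR-19b-1-5p, not well above background on the 10 and 15 nM arrays, was also lower (adjusted p = 0.0194 by limma), and lost its call under 5 alternatives and without each of 5 arrays, while let-7a-3p and let-7b-5p, at -0.37 and -0.19, did not pass.

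The other 7 lists did not pass for the mean of the 3 doses, with adjusted p from 0.284 to 0.981 by camera. miR-149-5p of the neuron-enriched list had a log2 difference of 0.41 that did not pass (adjusted p = 0.056 by limma), and miR-199a-5p of the mesenchymal list had -0.14. Values that did not pass were 0.14 for miR-30b-5p, which was -0.0033 with the total gene signal, 0.31 and -0.29 for miR-15a-5p and miR-16-2-3p, 0.23 and -0.07 for miR-29c-3p and miR-29b-3p, 0.30 and 0.25 for miR-23a-3p and miR-27a-3p, and -0.21 and -0.14 for miR-513b-5p and miR-513a-5p of Xq27.3, the latter 0.04 without replicate 2 of DMSO. The miR-29 family had a median of -0.05, a mean of 0.04 and an upward direction in camera. The mesenchymal list had a median of -0.10, which was 0.01 with normexp, and a mean of 0.08. When adjusted over the list alone the miR-30, neuron-enriched and mesenchymal lists had 1 higher member each, and by limma over all miRNAs 0, 1 and 1, which were miR-129-2-3p and miR-22-3p. The 1 higher of the miR-30 family, miR-30a-5p, was not well above background on the DMSO arrays (adjusted p = 0.0509 over all). Lists with fewer than 3 measured members were not tested. In these miR-26b-5p and miR-26a-5p had 0.10 and 0.05, miR-371b-5p and miR-371a-5p 0.33 and 0.15, and miR-107, of the p53-induced list, 0.01. Without scaling miR-26b-5p, miR-26a-5p and miR-107 had -0.02, -0.06 and -0.10, with the total gene signal miR-371a-5p had -0.30, and without replicate 2 of DMSO miR-26b-5p and miR-107 had -0.04 and -0.05. miR-96-5p was higher (adjusted p = 0.027 by limma), and lost its call with 4 scalings and without each of 7 arrays. The miR-96-5p values in DMSO and at 5 nM lay at the floor, so these groups added no spread to its test. The C19MC, miR-200, miR-449, blood cell, and muscle and liver lists had 0 measured members.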

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

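The tests in this part were chosen after the result was seen, except that of array-to-array differences for the miR-17-92 and C14MC lists. Intervals are 95% bootstrap intervals over miRNAs, which are not independent, unless said otherwise. Of 30 comparisons with DMSO of the 10 control features detected on all arrays, 2 lay above both DMSO arrays by more than these differed, and 2 below. The feature hur_4 was 0.342 higher at 10 nM on the log2 scale after scaling, and mr_1 was 0.166 higher at 5 nM. What they target is not given in the sources used here. All 10 features had higher means at 5 nM than in DMSO, as dmr_285 by 0.231, so that rise was not particular to mr_1. Before scaling the 75th percentiles were 302.3 and 250.6 at 5 nM, against 329.6 and 370.1 in DMSO. Scaling thus raised the 5 nM signals relative to DMSO. At 15 nM hur_6 and dmr_6 lay below, with differences of -0.285 and -0.227, and 8 of the 10 features had lower means there than in DMSO, against 4 at 10 nM and 0 at 5 nM.

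miRNAs with miRBase numbers over 600 made up 59 of the 73 rises at 15 nM and 14 of the 80 falls, and 200 of the 396 tested. Brighter arrays are argued against by slide 2, where the 15 nM array was dimmer than the DMSO array: 65 such miRNAs picked by their rise on slide 1 alone were a median of 0.495 higher there (0.373 to 0.675). Array-to-array differences unrelated to dose cannot be told apart from the drug for these 65, since that rise exceeded the gap between the DMSO arrays by 0.0395 (-0.227 to 0.225), and picking on slide 1 widens that gap. RNA quality or handling also stays open, since no RNA quality values were used here. The 15 nM effect correlated at 0.444 across the 396 miRNAs with the DMSO array of slide 2 minus that of slide 1. The sign of that correlation follows from the order of subtraction, so it cannot decide the question. An effect of the drug stays among the open explanations, and over all 200 the median was 0.289 on slide 1 and 0.00403 on slide 2.

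The miR-17-92 and C14MC lists were lower at 15 nM. The 196 tested miRNAs with miRBase numbers up to 600 had a median of -0.166 there. A scaling pushed down by the rising miRNAs is argued against for miR-17-92, whose median with spike-in scaling was -0.428 (-0.607 to -0.249, 2 standard errors), but it stays open for C14MC at -0.159 (-0.320 to 0.00155), where the interval reaches 0. For array-to-array differences unrelated to dose, the slide 2 difference minus the gap between the DMSO arrays had a median of -0.202 (-0.307 to -0.0621) for miR-17-92 and -0.158 (-0.237 to -0.119) for C14MC. The falls on slide 2 were thus larger than that single gap. This cannot decide the question, since a single gap gives no spread between arrays and the intervals are over list members. An effect of slide position, which was the same for each group on both slides, is not in that gap. Such differences stay open for both lists. RNA quality or handling stays open for both, since the lists also differed between the DMSO arrays, without the drug. The array of slide 2 minus that of slide 1 had a median of -0.221 (-0.277 to -0.154) for miR-17-92 and -0.0727 (-0.111 to -0.0504) for C14MC. The sign follows from the order of subtraction and has no bearing on the direction of the fall. An effect of the drug on either list stays among the open explanations.

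miR-129-2-3p was already higher at 5 nM. A fault of 1 probe is argued against by its other probe, which was 1.77 higher at 5 nM, and an outlying DMSO array by the smaller rise within a slide, 1.72, beside a gap between the DMSO arrays of 0.311. A response of this miRNA at the lowest dose is consistent with these values, as a hypothesis.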

How the results depend on the processing

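The deposited means, the spike-in scaling and the crossed pairing were chosen after seeing the data. Counts are of miRNAs past the threshold, and the cause of a change was not tested except where fewer arrays entered. The percentile over all probes gave 11 for 10 nM versus DMSO, 28 for the mean of the 3 doses and 81 for 15 nM versus 5 nM (65 higher, 16 lower, against 66 and 77). Quantile normalization gave 14 for 10 nM and 32 for the mean of the 3 doses (15 higher, 17 lower, against 29 and 21). No scaling gave 53 for 15 nM versus DMSO (41 higher, 12 lower, against 73 and 80), 3 for 10 nM (1 higher, 2 lower), 8 for the mean of the 3 doses, 69 for 15 nM versus 5 nM (0 lower) and 77 for the slope (64 positive, 13 negative, against 75 and 82). Spike-in scaling with the replicate block gave 69 for 15 nM (59 higher, 10 lower), 1 for 10 nM (0 lower), 8 for the mean of the 3 doses, 72 for 15 nM versus 5 nM (71 higher, 1 lower) and 92 for the slope (79 positive, 13 negative). Normexp changed the split to 35 higher and 16 lower for the mean of the doses and to 45 and 102 for 15 nM versus 5 nM, and the deposited means to 58 and 42 for the latter. The total gene signal, with 511 miRNAs tested, gave 74 higher and 119 lower for 15 nM, and 79 positive and 131 negative slopes. For 5 nM versus DMSO the mean of all probes gave 2, no filter 2 and the total gene signal 7. Only the 2 groups compared gave 68 for 15 nM, 1 for 10 nM and 0 for 5 nM, where limma gave 32 at an unadjusted p under 0.05. For the mean of the 3 doses, 0 of the lists passed with an estimated correlation, and fry called 2.

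The replicate block gave 152, 24, 1 and 41 calls for 15, 10 and 5 nM and the mean of the 3 doses versus DMSO, 149 for 15 nM versus 5 nM and 162 for the slope, and 3 lists passed with it. Of the calls named for a comparison, it ended those on miR-6821-5p and miR-96-5p at 10 nM and miR-29b-3p at 15 nM (adjusted p = 0.0646, 0.0547 and 0.0514) and changed no other, and the crossed pairing gave 169 for 15 nM. Leaving out each array in turn gave 59 to 159 for 15 nM, 1 to 45 for 10 nM, 0 to 1 for 5 nM, 16 to 81 for the mean of the 3 doses, 21 to 165 for 15 nM versus 5 nM, 87 to 169 for the slope and 2 to 4 for the lists. Over the alternatives 1230 values of named miRNAs kept their direction and their side of the threshold, 154 lost their call, 13 gained one and 25 changed sign; with an array left out these were 709, 107, 7 and 9. None of the values that changed sign passed the test before or after. The let-7 list lost its call under 6 alternatives to the values and without each of 3 arrays, and the list of miR-23, miR-27 and miR-24 clusters gained one without replicate 1 of the 15 nM group (adjusted p = 0.0494 by camera). The changed signs were as follows, and their cause was not tested. For the mean of the 3 doses miR-107 had -0.014 with normexp, -0.076 with the percentile over all probes, -0.085 with quantile normalization, -0.10 without scaling, -0.021 with the mean of all probes, -0.13 with the total gene signal and -0.074 with the deposited means. miR-26a-5p had -0.032 with the percentile over all probes, -0.059 without scaling and -0.079 with the total gene signal, and miR-26b-5p had -0.015 and -0.029 under the latter 2. With the total gene signal miR-371a-5p had -0.30 and miR-30b-5p -0.0033. At 15 nM miR-30b-5p had -0.043 with the percentile over all probes, -0.22 with the total gene signal and -0.0043 with the deposited means, and miR-30d-5p had -0.019, -0.013 and -0.19 with that percentile, quantile normalization and the total gene signal. miR-30e-5p had 0.052 without scaling and 0.15 with spike-in scaling, and miR-30c-5p 0.018 with the latter. At 5 nM miR-431-3p and miR-4449 had 0.050 and 0.033 with normexp. List medians for the mean of the 3 doses that changed sign, in lists that did not pass, were 0.0058 for the mesenchymal list with normexp and -0.0016 for the miR-30 family with the total gene signal. With the percentile over all probes, no scaling and the total gene signal they were -0.022, -0.049 and -0.13 for the miR-15 and miR-16 family and -0.0083, -0.029 and -0.048 for the neuron-enriched list. Leaving out each array in turn gave ranges across 0 of -0.052 to 0.068 for miR-107, -0.042 to 0.23 for miR-26b-5p, -0.32 to 0.038 for miR-513a-5p and -0.36 to 0.038 for the Xq27.3 list in the mean of the doses, and at 15 nM of -0.085 to 0.11 for miR-30b-5p, -0.16 to 0.24 for miR-30d-5p and -0.13 to 0.037 for miR-30e-5p.

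Signal over background limits dim miRNAs, since 1873 of 2549 lay at the floor on every array.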

Other observations

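The tests on hairpin arms and the miRNAs named in this part were chosen after their values were seen, and the test on gene position was not. Outside the lists, miR-375, a neuroendocrine miRNA, fell by 0.68 on the log2 scale at 15 nM (adjusted p = 0.0383 by limma), and miR-374a-5p and miR-374b-5p, near relatives in sequence, fell by 0.55 and 0.57. miR-320c rose by 0.59 and miR-181a-5p by 0.53 (adjusted p = 0.00568 and 0.0230 by limma), and miR-320c was also called at 10 nM. miR-1246 and miR-1290 rose by 1.18 and 0.94, and both carry miRBase numbers over 600.

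Both arms of 27 hairpins were measured, and in 22 of them both had the same direction at 15 nM. Their log2 fold changes correlated with a Spearman rho of 0.646 across hairpins, which are not independent (two-sided permutation test with 100000 permutations, p = 0.00042, adjusted p = 0.00084 over 2 tests). The 17 hairpins outside C14MC gave 0.642 (permutation p = 0.00701). This is consistent with changes of the precursor or its transcript, as a hypothesis, though differences between arrays that move both arms were not separated from it. A second hypothesis, that the fall within C14MC differs with the position of the gene, gave a rho of 0.00543 over its 50 members and did not pass (two-sided permutation p = 0.970, adjusted p = 0.970 over the same 2 tests).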
